A study of Mus musculus with 12 samples.

How the data were processed

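Total RNA was measured in the mouse fibroblast line NIH3T3, an immortalised line from mouse embryos, and in 3 clonal derivatives of it in which Aebp1 was knocked out, named F5, G5 and H7 in the labels. The parental line was sampled at passages 6, 7 and 8 and each clone at passages 7, 8 and 9, which gave 12 libraries in 4 groups of 3. Per the labels' protocols, the cells grew in DMEM/F12 medium with fetal bovine serum, ribosomal RNA was depleted, stranded total-RNA libraries were made, and the pooled libraries were sequenced from both ends. The labels give the passage number of each library but do not say that passages were separate cultures, so p-values measure only the spread between these samples. The parental line is a single uncloned population and each clone grew from a single cell. Cloning and the loss of Aebp1 are therefore present together in every clone and in no parental library.

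The authors deposited a table of estimated counts for 48795 Ensembl genes and a second table of the same genes in TPM. The deposited counts are not normalised and are not whole for every gene: 86.9% of the values above 0.5 lay within 0.01 of a whole number, and the rest were rounded for the tests. Every column of the deposited TPM table summed to 1000000, so its values were taken as TPM. The submitters' processing notes name the build GRCm38. The aligner, the counting tool, the annotation release and the use of strand in counting are not given in the sources used here. Identifiers were matched to GENCODE release M21, which gave a symbol to 48435 of them, and coordinates are those of GRCm38 in that release, counted from 1. Reads of near-identical genes may have been split or pooled between copies: Rn7s1 took between 0.0141% and 1.99% of the counts of a library and Rn7s2 between 0.791% and 3.13%. Together they took 3.15% to 3.30% in the parental libraries and 2.26% to 2.96% in the clone libraries. Overlapping and antisense genes carry the same uncertainty.

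Library totals lay between 22088695 and 31329735 counts. Counts per 1000000 counts (CPM) use edgeR's TMM factors. Where a group had 0 counts of a gene, the limit is 3 counts over the summed libraries of the group, or 0.0426 CPM in the parental line, 0.0358 in F5, 0.0398 in G5 and 0.0386 in H7. A ratio against a group with 1 to 3 counts carries a 95% counting interval. These limits and intervals cover counting error only.

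Genes were kept by edgeR's filterByExpr on the 4 groups, which left 14704. The main test was edgeR's quasi-likelihood F-test on the rounded counts, with TMM factors, group as the only term, and all 12 libraries in 1 fit with 8 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called without a fold threshold. Every adjusted p printed for a gene is from this test unless another tool is named. Standard errors of log2 fold changes were taken from the F statistic. The biological coefficient of variation was 15.5% between libraries of a group. The comparisons were the mean of the 3 clones against the parental line, each clone against the parental line, each clone against each other clone, and a trend with the passage number within groups. Genes called in the same direction in all 3 clones are the intersection of the clone calls. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15.

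Gene groups were 30 lists of genes, fixed with their members before the data were examined, as were the comparisons, the tests, the alternatives listed below, other than the 7 added, and the rule for naming genes. Each list was tested with limma's camera on log2 CPM at a preset correlation of 0.01, and again with a correlation estimated from the residuals and with fry. Counts of changed list members are given over all genes tested and again adjusted over the list alone. The rule named Aebp1. It named the 10 higher and 10 lower genes whose smallest change over the 3 clones was largest, among genes called alike in all clones with a mean of at least 1 CPM and a symbol that is not a predicted-gene name. It named up to 4 members of each list with the smallest adjusted p. For each clone it named 4 higher and 4 lower genes that were called in that clone and not in either other clone, and it named the 6 genes with the largest difference between clones among those called in opposite directions. Imprinted genes, mitochondrial genes, genes differing between F5 and G5, and genes of the middle passage were picked after their values were seen.

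The tests were run on simulated counts drawn from the means and library sizes of the real samples, with 14534 genes passing the filter. For the mean of the 3 clones, 46 of 67 genes changed 1.5-fold were recovered, 61 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 9 false calls. For clone F5 against the parental line the numbers were 31 of 67, 50 of 67 and 63 of 66, with 8 false calls. For F5 against G5, simulated with no change, edgeR made 0 calls. In the simulated set, camera called 0 of 100 random lists that had not been shifted. Simulated genes were drawn independently, whereas real list members correlate (estimated correlation 0.9 for the S-phase list). This check therefore does not show how often camera calls real lists by chance.

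Passages 7 and 8 occur in all groups, and passage 9 in the clones. Deviations from the group means were compared between libraries of the same passage number. Between clones, all 9 such pairs correlated positively, with r between 0.15 and 0.50 across genes, and the 18 pairs of other passage numbers lay between −0.51 and 0.02. The passage numbers of the labels thus pair the clones with one another. Parental and clone libraries of the same number correlated between −0.53 and −0.19 over 6 pairs, so the number does not pair those. A fit with the passage as a block was run for the genes the rule named, the lists and the counts of calls. In comparisons with the parental line this block joins libraries that do not pair. Calls that it ends or begins there show only how they depend on that setting.

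The alternatives were DESeq2, limma-voom, limma on log2(TPM + 1) and on log2(TPM + 0.1), other scaling factors, other filters, stricter thresholds, fits on fewer groups, counts summed per line, a passage term or block, and leaving out each library in turn. After the data were examined, 7 more were added: a block for the place of a library in the order of passages of its group, the same block with an estimated correlation for lists, removal of each clone's chromosome medians, a fit without the middle passage of every group, lists with an estimated correlation without each library, lists compared between clones, and the carboxypeptidases without Aebp1. Protein levels, the edited sequence of Aebp1 and effects on tumours or on immune therapy were not analysed here.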

Results

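Ribosome-depleted total RNA was sequenced from NIH3T3 fibroblasts and from 3 clones of that line, F5, G5 and H7, in which Aebp1 had been knocked out. AEBP1 is a secreted, collagen-binding protein with a carboxypeptidase-like domain. The title of the series places it in cancer-associated fibroblasts, the connective-tissue cells of tumours. Each of the 4 groups held 3 libraries, taken at passages 6, 7 and 8 of the parental line and at passages 7, 8 and 9 of each clone. Library totals ran from 22088695 to 31329735 counts, and a median of 18443 genes per library had at least 1 count. Gm26917, a ribosomal-RNA-like transcript, took between 6.83% and 9.54% of the counts of a library.

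On a plot of the distances between libraries, the H7 libraries lay apart from the F5 and G5 libraries along the first dimension, with 37.7% of the variance. The parental libraries lay apart from all clones along the second, with 27.0%. The parental library of passage 7 stood farther out than the other parental libraries, at −2.26 on the second dimension against −1.26 and −1.41. The middle passage also lay lowest on that dimension within each clone, at 0.16 in F5, 0.484 in G5 and 0.319 in H7.

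**Figure D1:**
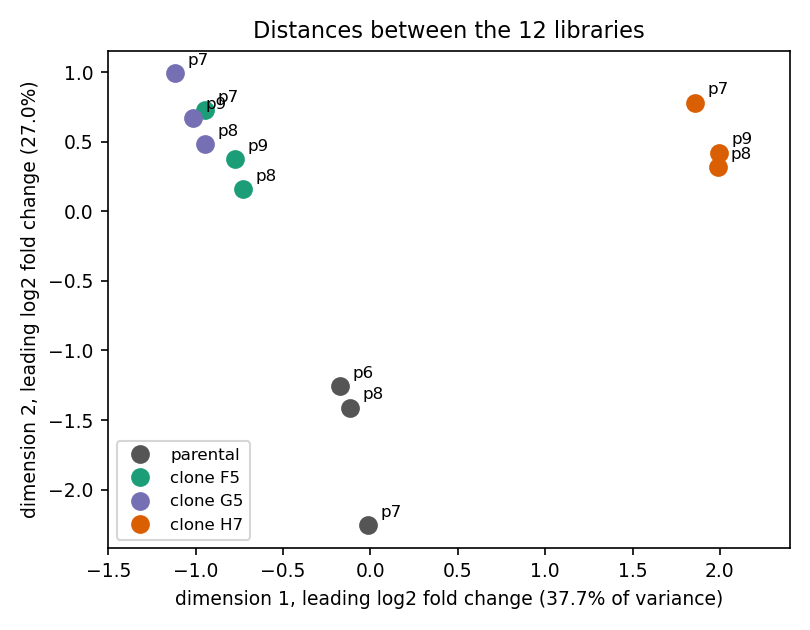
Multidimensional scaling of the 12 libraries on the 500 genes with the largest pairwise log2 fold changes; each point is 1 library, labelled with its passage, and the axes are leading log2 fold changes. The 3 H7 libraries lie between 1.86 and 1.99 on dimension 1, and all F5 and G5 libraries lie below −0.72.

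The targeted gene was measured first. Aebp1 (ENSMUSG00000020473), on chromosome 11 from 5861947 to 5872088 on the plus strand of GRCm38, stood at 553 ± 76.6 CPM in the parental line (mean and SD, n = 3). It stood at 193 ± 19.9 CPM in F5, 128.3 ± 8.46 in G5 and 147 ± 14.4 in H7 (n = 3 each), or 34.9%, 23.2% and 26.6% of the parental level. The log2 fold change was −1.52 (SE 0.12, adjusted p = 3.6e-05) in F5, −2.11 (SE 0.12, adjusted p = 9.24e-06) in G5 and −1.91 (SE 0.12, adjusted p = 3.26e-06) in H7. All 9 knockout libraries lay below all 3 parental libraries, so the gene measurement went the way of the labels. The transcript remained detectable in every clone, and counts per gene do not show whether it still encodes the protein; the edited position is not given in the sources used here.

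**Figure D2:**
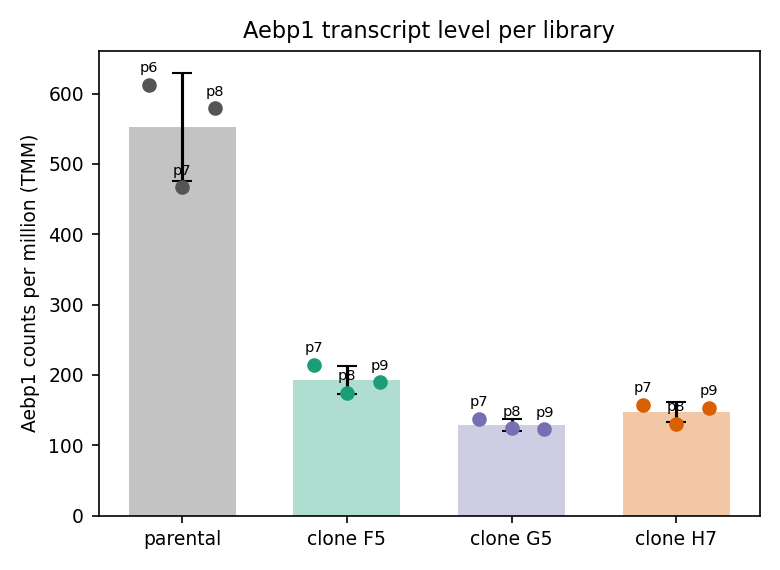
Aebp1 level in CPM (counts per 1000000 counts) for each library (points, labelled with the passage), with the group mean (bar) and standard deviation (error bar, n = 3). The parental mean is 552.9 and the clone means are 193, 128.3 and 147.3.

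The clones together were compared with the parental line to ask what expression changes go with the loss of Aebp1. Genes that rose in all 3 clones included Car6, a secreted carbonic anhydrase, which went from 1.69 ± 0.684 CPM to 19.3 ± 9.52 in F5, 24.3 ± 15.8 in G5 and 40.3 ± 8.49 in H7 (n = 3 each). Cdsn, an adhesion protein of the cornified skin layer, went from 12.1 ± 5.11 CPM to 116 ± 62.1, 121 ± 66.1 and 112 ± 28.6. Stbd1, a glycogen-binding protein, rose from 1.10 ± 0.348 CPM to at least 10.3 in each clone, a log2 fold change of 3.39 (SE 0.34, adjusted p = 9.85e-05) for the mean of the clones. Lower in all 3 clones were Vip, a neuropeptide, which fell from 15.6 ± 2.49 CPM to 0.218 ± 0.19, 0.409 ± 0.261 and 0.662 ± 0.30, and Eln, which encodes elastin and fell from 5.44 ± 2.97 CPM to 0.057, 0.0118 and 0.116. Igf2, a fetal growth factor, fell from 341 ± 394 CPM to 3.36 ± 3.07, 2.80 ± 2.77 and 17.5 ± 11.

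The rule named further genes that rose in all 3 clones. Sspo, Ostn, Angpt1, Taf7l, Sh3bgrl2, Atp2a3 and Gdap1l1 stood between 0.0442 and 0.289 CPM in the parental line and between 1.06 and 5.88 CPM in the clones. Angpt1, a ligand of the endothelial TEK receptor, had a log2 fold change of 4.44 (SE 0.53, adjusted p = 0.00029), or 5.06 without parental passage 7, and Atp2a3, a calcium pump of the endoplasmic reticulum, one of 3.63 (SE 0.56, adjusted p = 0.00143), or 4.43 without parental passage 6. Ostn rested on 3 counts in the parental line, against 93, 116 and 459 in the clones.

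The 10 lower genes that the rule named included 4 genes of the Y chromosome. Kdm5d, a histone demethylase, Ddx3y, an RNA helicase, and Eif2s3y, a translation initiation factor, had 0 counts in G5 and in H7. They were lower than in the parental line by at least 235-fold, 474-fold and 216-fold in G5 and by at least 242-fold, 488-fold and 223-fold in H7. In F5 these genes had 7, 20 and 13 counts, against 662, 1323 and 604 in the parental line. Uty, the fourth, fell from 9.01 ± 0.193 CPM to 0.214, 0.187 and 0.142. B4galnt4, a glycosyltransferase, had 422 counts in the parental line, 0 in F5, 4 in G5 and 0 in H7, at least 167-fold lower in F5 and at least 155-fold lower in H7.

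H19, an imprinted non-coding RNA next to Igf2, fell from 43.3 ± 45.4 CPM to 1.73, 1.03 and 1.39, and Dapk1, a death-associated kinase, fell from 15.0 ± 13.4 CPM to 0.456, 0.313 and 0.936. The parental library of passage 7 raised these parental means. Without it, the log2 fold change of Igf2 moved from −5.96 to −4.37, that of H19 from −5.00 to −3.69 and that of Dapk1 from −4.87 to −3.82. The adjusted p without it was at most 0.00142 for these 3 genes. That library is the middle passage of its group, and Igf2 and H19 were highest in the middle passage in all 4 groups. Wherever it alone is left out, the clones keep their middle passage and the parental line does not.

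In all, 1257 genes rose and 1543 fell in the mean of the clones, of 14704 tested, and the median size of the called changes was 0.48 on the log2 scale. In all 3 clones, 374 genes rose and 314 fell. On the deposited TPM values, limma called 1294 higher and 889 lower for the mean with log2(TPM + 1) and 1292 and 880 with log2(TPM + 0.1), and 321 and 170, or 336 and 149, in all 3 clones, a larger share of higher calls. With counts summed per line, so that 3 clones were set against 1 parental line, edgeR called 0 genes (1735 at an unadjusted p under 0.05) and DESeq2 called 650, and treating the 9 knockout libraries as 1 group gave 1356 calls in place of 2800. Since the second passages of all groups deviated alike, a block for the place in the order of passages, chosen after the data were examined, gave 4908 calls for the mean of the clones and 1546 genes changed alike in all clones; fits on 6 libraries each gave 219 such genes, and leaving out H7 passage 7 gave 456 in place of 688.

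Among the extracellular matrix proteins outside the fibrillar collagens, 1 of 36 measured genes rose and 15 fell in the mean of the clones (1 and 17 adjusted over the list alone). Camera called the list lower (adjusted p = 0.000144), and the adjusted p = 0.532 with an estimated correlation. In F5 2 rose and 12 fell (2 and 17 adjusted over the list alone) and in G5 1 and 12 (2 and 14), with camera adjusted p = 5.92e-05 and 1.68e-05, and adjusted p = 0.525 and 0.396 with an estimated correlation. In H7 6 fell, as adjusted over the list alone, and camera did not call the list (adjusted p = 0.165). It did not call the difference of F5 or G5 from H7 either (adjusted p = 0.0989 and 0.0629). Col6a2, a chain of the pericellular collagen VI, fell from 1131 ± 105 CPM to 664 ± 34.4, 625 ± 33 and 671 ± 78.1 in F5, G5 and H7, a log2 fold change of −0.79 (SE 0.07, adjusted p = 7.3e-05). Tgfbi, a matrix protein induced by TGF-β, fell from 44.2 ± 18.1 CPM to 6.02 ± 1.66 in F5 and 0.292 ± 0.192 in G5, and stood at 50.3 ± 11.8 in H7 (adjusted p = 0.721). The fall of Eln belongs to the same list. Among fibrillar collagens and collagen-crosslinking enzymes, 4 of 23 rose and 9 fell, with the same counts adjusted over the list alone, and camera did not call the list (adjusted p = 0.145). The lysyl hydroxylase Plod2 rose from 14.6 ± 2.89 to between 27.1 and 31.1 CPM, with a log2 fold change of 1.01 (SE 0.12, adjusted p = 0.000248), and the prolyl hydroxylase subunit P4ha1 rose by 0.53 (SE 0.08, adjusted p = 0.00107). Col11a1 fell in F5 and G5, with log2 fold changes of −2.06 and −2.50, and rose by 1.23 in H7. Col12a1 fell by 2.45 in the mean of the clones, and stood at −1.48 without the parental library of passage 7.

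Among contractile and myofibroblast genes, 3 of 20 rose and 1 fell, as adjusted over the list alone, and camera gave an adjusted p = 0.117 (0.027 by fry, and adjusted p = 0.644 by camera with an estimated correlation). Acta2, the smooth-muscle actin that marks myofibroblasts, rose from 326 ± 42.3 CPM to 579 ± 13.2, 621 ± 19.8 and 537 ± 77.9, a log2 fold change of 0.83 (SE 0.10, adjusted p = 0.00024). Actg2, its gut paralog, rose by 1.51 (SE 0.19), and Cnn1, a calponin of contractile fibres, fell by 1.25 (SE 0.25, adjusted p = 0.00553). In TGF-β signalling, 1 of 27 genes rose and 6 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.162, or 0.0396 without the parental library of passage 7, where the adjusted p = 0.64 with an estimated correlation). The inhibitory Smad6 fell by 0.92 (SE 0.17, adjusted p = 0.00378) and the signal transducer Smad3 fell by 0.48 (SE 0.10, adjusted p = 0.00631). Of the targets of YAP and TEAD, 3 of 21 rose and 4 fell, alike when adjusted over the list alone (camera adjusted p = 0.569). Of the metalloproteinases and their inhibitors, 2 of 18 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.643). Mmp11, the stromelysin of tumour stroma, rose by 0.63 (SE 0.13, adjusted p = 0.00626), by 1.03 in F5 and in G5, and stood at −0.16 in H7 (adjusted p = 0.514). Of the fibroblast identity genes, 1 of 19 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.643). Prrx1, a mesenchymal transcription factor, fell by 0.46 (SE 0.10, adjusted p = 0.0093), and Cd34 rose in H7 by 1.79 (SE 0.19).

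Of the p53 targets, 14 of 29 rose and edgeR called 0 lower (19 and 1 adjusted over the list alone; 20 genes at an unadjusted p under 0.05; DESeq2 called 18 higher and 0 lower). Camera gave an adjusted p = 1.1e-08, and the adjusted p = 0.162 with an estimated correlation. Of these genes 12 rose in all 3 clones. Gadd45a, a DNA-damage-inducible growth-arrest gene, rose from 2.73 ± 0.694 CPM to 14.4 ± 3.45, 15.8 ± 3.46 and 13.1 ± 2.05. Plk2, a stress-induced kinase, rose by 0.93 (SE 0.07, adjusted p = 1.36e-05), and Trp53inp1, a stress-induced partner of p53, rose by 1.38 (SE 0.15, adjusted p = 0.000189). Of the genes of the unfolded protein and integrated stress responses, 18 of 32 rose and 5 fell (18 and 7 adjusted over the list alone). Camera gave an adjusted p = 0.000129, and the adjusted p = 0.384 with an estimated correlation. Atf4, the central transcription factor of the integrated stress response, rose from 304 ± 21.8 CPM to 521 ± 30.6, 552 ± 44.8 and 470 ± 20.7. Its targets Trib3 and Slc7a11 rose by 2.13 (SE 0.20) and 2.06 (SE 0.28), and Ddit4 and Sesn2, inhibitors of mTORC1, rose by 1.45 (SE 0.11) and 1.00 (SE 0.09).

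Of the hypoxia and glycolysis genes, 19 of 32 rose and 1 fell (23 and 1 adjusted over the list alone). Camera gave an adjusted p = 2.6e-10, and the adjusted p = 0.162 with an estimated correlation. Ero1l, an oxidase of the endoplasmic reticulum, rose by 2.13 (SE 0.24, adjusted p = 0.000225), Bnip3, a mitophagy receptor, by 0.88 (SE 0.09, adjusted p = 9.29e-05), and the angiogenic factor Vegfa by 0.86 (SE 0.11, adjusted p = 0.000598). The glycolytic enzyme Tpi1 rose by 0.66 in F5 and by 0.55 in G5, and stood at 0.16 in H7 (adjusted p = 0.153). Of the nuclear-encoded genes of oxidative phosphorylation, 6 of 40 rose and 1 fell (12 and 1 adjusted over the list alone). Tested by camera, it had an adjusted p = 0.0351, and the adjusted p = 0.644 with an estimated correlation. Without the parental library of passage 7 its adjusted p was 0.491, and by fry it was 0.124. In H7 12 rose (15 and 1 lower adjusted over the list alone), with a camera adjusted p = 0.000837 and an adjusted p = 0.669 with an estimated correlation. In F5 and in G5 2 rose and 1 fell (2 and 1 in F5 and no gene in G5 adjusted over the list alone), and camera called the list in neither (adjusted p = 0.104 and 0.638). The list was lower in G5 than in H7 (adjusted p = 0.0084, and adjusted p = 0.913 with an estimated correlation), and F5 against H7 gave 0.0989. Ndufb9, a subunit of complex I, rose by 0.34 in the mean and by 0.80 (SE 0.07, adjusted p = 5.52e-05) in H7. Ndufb9 lies on chromosome 15, whose 419 expressed genes had a median log2 fold change of 0.47 in H7. Lists were not tested with each clone's chromosome medians removed. How far shifts of whole chromosomes enter the H7 result of this list was therefore not tested. Of the NRF2 and glutathione genes, 3 of 26 rose and edgeR called 0 lower (8 genes at an unadjusted p under 0.05; DESeq2 called 1 lower), alike when adjusted over the list alone (camera adjusted p = 0.154, or 0.0224 without the parental library of passage 8, where the adjusted p = 0.625 with an estimated correlation). Gstp1, a glutathione transferase, rose by 0.38 (SE 0.09, adjusted p = 0.0143, or 0.0846 with the passage block). Of the cholesterol synthesis genes, 1 of 24 rose and 2 fell, as adjusted over the list alone (camera adjusted p = 0.213). In H7, 13 of these 24 fell and 1 rose (19 and 1 adjusted over the list alone), with a camera adjusted p = 2.4e-05 and an adjusted p = 0.669 with an estimated correlation. Lss, lanosterol synthase, fell there by 1.27 (SE 0.09, adjusted p = 7.63e-06).

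Of the inflammatory fibroblast cytokines, 1 of 15 rose and 5 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.0517). In F5 1 rose and 8 fell (1 and 10 adjusted over the list alone; camera adjusted p = 0.00745, and adjusted p = 0.168 with an estimated correlation). In G5 1 rose and 7 fell (1 and 9 adjusted over the list alone; camera adjusted p = 0.00815, and adjusted p = 0.174 with an estimated correlation). In H7 4 rose and 3 fell, as adjusted over the list alone (camera adjusted p = 0.638). For the mean, camera called the list lower without parental passage 6 (adjusted p = 0.041), parental passage 7 (0.0382), G5 passage 7 (0.0431) or G5 passage 8 (0.0477). It also called the list lower with the passage block (0.0382) and the block for the order of passages (0.0258), and fry gave 0.00712. With an estimated correlation the adjusted p was 0.384, at least 0.298 without each of these libraries, and 0.239 with the block for the order of passages. Camera called the list lower in F5 and in G5 than in H7 (adjusted p = 0.013 and 0.0114, and adjusted p = 0.516 and 0.363 with an estimated correlation). Il1r1, the interleukin-1 receptor, fell from 140 ± 39.2 CPM to 76.0 ± 8.38, 75.4 ± 10.1 and 84.2 ± 11. Has2, a hyaluronan synthase, fell by 1.11 (SE 0.18, adjusted p = 0.00167), and the chemokine Cxcl12 fell by 1.97, or to −1.14 without the parental library of passage 7. Of the NF-κB genes, 1 of 20 rose and 6 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.0517, or 0.047, 0.0431 and 0.0443 without parental passage 8, G5 passage 7 and H7 passage 7, and 0.00095 by fry). With an estimated correlation the adjusted p was 0.216, and at least 0.213 without each of these libraries. In F5 1 rose and 8 fell (1 and 9 adjusted over the list alone) and in G5 1 and 5 (1 and 7), with camera adjusted p = 0.0331 and 0.00885, and adjusted p = 0.168 and 0.146 with an estimated correlation. In H7 3 rose and 3 fell, as adjusted over the list alone (camera adjusted p = 0.691). The differences of F5 and G5 from H7 were not called (adjusted p = 0.0989 and 0.0661). Vcam1, an adhesion receptor for leukocytes, fell by 0.71 (SE 0.12, adjusted p = 0.00266), and Birc3, an inhibitor of cell death, fell by 0.60 (SE 0.11). Of the type I interferon-stimulated genes, 3 of 21 fell and edgeR called 0 higher (8 genes at an unadjusted p under 0.05; DESeq2 called 0 higher and 3 lower), and 1 fell when adjusted over the list alone. The list had a camera adjusted p = 0.0497, and the adjusted p = 0.644 with an estimated correlation. The list was not called without parental passage 7 (adjusted p = 0.693), F5 passage 7 (0.0532), F5 passage 9 (0.0583) or H7 passage 9 (0.0557), nor by fry (0.145), with library sizes in place of TMM factors (0.0501) or with a prior count of 0.5 (0.0504). Usp18, a brake on interferon signalling, fell by 2.48 (SE 0.46, adjusted p = 0.00395), while the calls of Ddx58 and Parp14 ended without the parental library of passage 7 (adjusted p = 0.288 and 0.763); that of Parp14 also ended with the passage block (0.0973). Of the antigen presentation genes and ligands of PD-1, 3 of 24 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.691). Cd74, the invariant chain of class II molecules, had 2 counts in the parental line and 24, 26 and 144 in the clones; the parental level was 0.0153 of that in H7 (95% counting interval 0.00184 to 0.0563). Both parental counts lay in the library of passage 7. Without it Cd74 stood at least 27.9-fold higher in H7, against 3 counts over the 2 other libraries, and the fitted log2 fold change of the mean, which depends on the prior count, moved from 4.13 to 6.89. B2m, the light chain of class I molecules, fell by 0.33 (SE 0.07, adjusted p = 0.0114), and H2-D1, a class I heavy chain, rose by 0.29 (SE 0.06, adjusted p = 0.00521).

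Of the Wnt genes, 1 of 19 rose and 7 fell (3 and 11 adjusted over the list alone). Tested by camera, it had an adjusted p = 0.0425, and the adjusted p = 0.216 with an estimated correlation. Its call ended without parental passage 6 (adjusted p = 0.0557), without parental passage 7 (0.0631) and with library sizes in place of TMM factors (0.0501). The secreted Wnt antagonists Sfrp1 and Sfrp2 fell, with log2 fold changes of −2.90 and −4.02, or −1.91 and −2.51 without the parental library of passage 7, and the transcription factor Tcf7l2 fell by 0.32 (SE 0.06, adjusted p = 0.00283). Of the adipocyte genes, 4 of 15 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.805). The median and mean of that list were −0.20 and −0.08, while the test ranked it as higher. Plin2, which coats lipid droplets, rose by 0.71 (SE 0.07, adjusted p = 0.000138), and Dlk1, an inhibitor of fat-cell formation, fell from 3040 ± 1010 CPM to 1617 ± 186, 1479 ± 158 and 1633 ± 46.4. Of the immediate early and MAPK targets, 2 of 26 rose and 8 fell, as adjusted over the list alone (camera adjusted p = 0.0517, or 0.009, 0.0324, 0.0206 and 0.0342 without parental, F5, G5 and H7 passage 7, and 0.00403 with the block for the order of passages). With an estimated correlation the adjusted p was 0.644, at least 0.528 without each of these libraries, and 0.428 with that block. In F5 6 fell (2 higher and 8 lower adjusted over the list alone) and in G5 1 rose and 5 fell (2 and 7), with camera adjusted p = 0.043 and 0.0263, and adjusted p = 0.753 and 0.597 with an estimated correlation. In H7 1 rose and 1 fell, as adjusted over the list alone (camera adjusted p = 0.574), and the differences of F5 and G5 from H7 were not called (adjusted p = 0.302 and 0.194). Fos and Junb, subunits of AP-1, fell, with log2 fold changes of −1.27 (SE 0.23) and −0.62 (SE 0.12). Of the HOX genes, 1 of 22 rose and 8 fell (1 and 9 adjusted over the list alone). The list had a camera adjusted p = 0.0451, and the adjusted p = 0.545 with an estimated correlation. The genes went both ways in H7, where 6 rose and 9 fell (camera adjusted p = 0.403). In F5 1 rose and 3 fell (camera adjusted p = 0.139), and in G5 3 fell (camera adjusted p = 0.0436, and adjusted p = 0.516 with an estimated correlation), with the same counts in each clone adjusted over the list alone. The call for the mean ended without parental passage 7 (adjusted p = 0.443), without H7 passage 8 (0.0551), with the block for the order of passages (0.0631) and with library sizes in place of TMM factors (0.0501). Hoxb9 stood at 0.371 ± 0.159 CPM in the parental line, 2.38 ± 0.148 in F5, 0.426 ± 0.164 in G5 and 13.0 ± 1.23 in H7. Hoxa10 had 0 counts in H7, at least 54.8-fold lower than in the parental line. Hoxc8 fell in F5 and G5, with log2 fold changes of −1.76 and −3.04, and rose in H7 by 1.78; its mean change of −1.01 (adjusted p = 0.00054) reversed to 0.36 when the knockout libraries formed 1 group (adjusted p = 0.882) and to 0.37 when counts were summed per line (adjusted p = 0.962). Of the carboxypeptidases, the relatives of AEBP1, 3 of 7 fell, Aebp1 among them, and 0 rose by edgeR or by DESeq2 (3 genes at an unadjusted p under 0.05), with the same counts adjusted over the list alone. Tested by camera, its adjusted p = 0.0351, and the adjusted p = 0.216 with an estimated correlation. The call rested on the targeted gene: without Aebp1, camera gave the 6 others an adjusted p = 0.149, or 0.532 with an estimated correlation, and fry gave 0.019. Cpxm1 fell by 1.21 (SE 0.25, adjusted p = 0.00675).

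The proliferation lists held few called genes. Of 32 genes of S phase, edgeR called 0 in the mean of the clones, over all genes or adjusted over the list alone, 0 lay at an unadjusted p under 0.05, and DESeq2 called 0. The median log2 fold change of the list was 0.04, and Mcm2, a subunit of the replicative helicase, stood at 0.18 (SE 0.14, adjusted p = 0.405), or at −0.01 without the parental library of passage 7. Of 32 genes of G2 and mitosis, 1 fell and 0 rose by edgeR, as adjusted over the list alone (2 at an unadjusted p under 0.05; DESeq2 called 1 higher and 1 lower). The lower gene was Ccnb2, a mitotic cyclin, which fell in H7 from 12.1 ± 1.69 CPM to 0.209 ± 0.165 and stood at 11.2 ± 1.75 in F5 and 12.3 ± 1.88 in G5. Camera called neither list (adjusted p = 0.519 and 0.643, and adjusted p = 0.934 for both with an estimated correlation). In a pooled test of the middle passages of the 4 groups, 30 of the S-phase genes and 31 of those of G2 and mitosis fell (31 and 31 adjusted over the list alone). Leaving out parental passage 7 alone removes the middle passage from the parental line and not from the clones, and camera then called both lists lower (adjusted p = 0.0417 and 0.0115, and adjusted p = 0.846 for both with an estimated correlation). It called neither with the block for the order of passages (adjusted p = 0.246, higher, and 0.484, lower) or without the middle passage of every group (0.271 and 0.0575, both lower).

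Few markers of other cell types were measured. Epithelial markers had 3 measured genes, of which 1 fell, adjusted over the list alone as well (Krt7, by 1.59; adjusted p = 0.0968 without the parental library of passage 7), and camera gave an adjusted p = 0.639. In H7 1 rose and 1 fell, as adjusted over the list alone (camera adjusted p = 0.574), and the higher one was Cdh1, E-cadherin, with 1 count in the parental line, 4 in F5, 3 in G5 and 57 in H7. Leukocyte and macrophage markers had 4, of which 1 fell, adjusted over the list alone as well (Ptprc, 0.434 CPM in the parental line and at most 0.211 in a clone; adjusted p = 0.0712 without that library and 0.0543 with the passage block), with a camera adjusted p = 0.987, a median of 0.15, a mean of −0.42 and a test direction of higher. Of 6 endothelial markers, 1 rose and 2 fell, alike when adjusted over the list alone (camera adjusted p = 0.587). Flt1, a VEGF receptor, rose from 3.98 ± 0.887 CPM to 13.3 ± 1.00 in F5 and 12.8 ± 1.30 in G5. Egfl7 fell from 4.49 ± 0.684 CPM to 0.457 in F5 and 0.218 in G5. In H7 edgeR called 0 of the 6 markers higher and 1 lower (2 lower adjusted over the list alone, camera adjusted p = 0.501). Of 4 skeletal muscle markers, 2 rose, alike when adjusted over the list alone (camera adjusted p = 0.117, 0.0432 by fry, and adjusted p = 0.611 by camera with an estimated correlation); Acta1, skeletal actin, stood at 0.146 CPM in the parental line and 1.31 ± 0.11 in H7. Of 10 chondrocyte and osteoblast markers, 1 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.111, or 0.0457 without the parental library of passage 7, and 0.0142 by fry; adjusted p = 0.611 with an estimated correlation), with Sox5, a cartilage transcription factor, lower by 1.00 (SE 0.11, adjusted p = 0.000189) on the log2 scale. Acan, which encodes aggrecan, had 125 counts in the parental line and 1, 2 and 10 in the clones. Of 7 neural and glial markers, 1 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.629), and Snap25, a synaptic vesicle fusion protein, fell from 11.8 ± 1.23 CPM to 1.99 ± 0.955 in F5 and 1.27 ± 0.485 in G5 and stood at 13.4 ± 1.52 in H7.

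**Figure D3:**
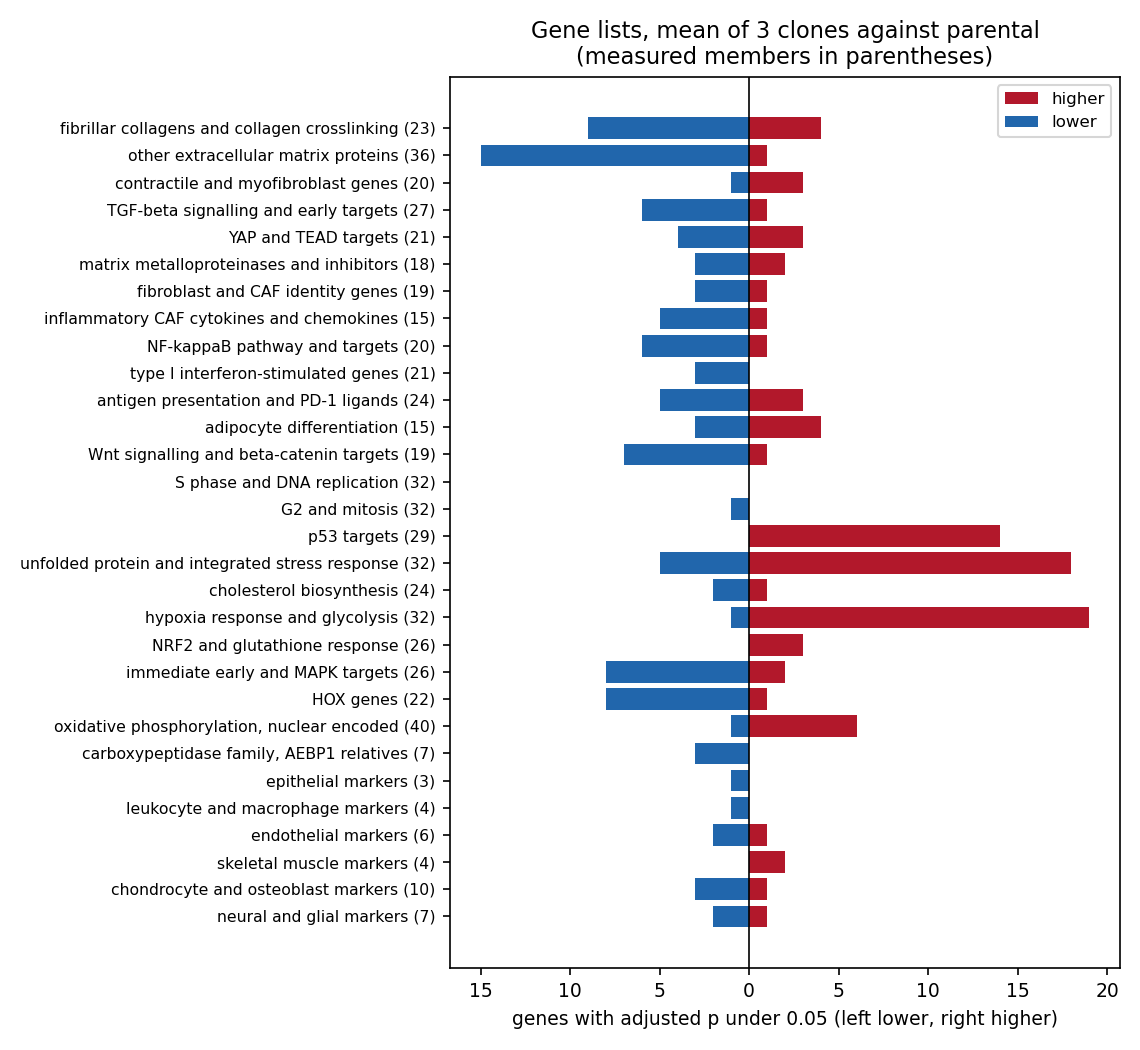
Number of genes of each list with an adjusted p under 0.05 for the mean of the 3 clones against the parental line (horizontal axis; higher to the right, lower to the left), with the number measured in parentheses. Hypoxia response and glycolysis has 19 higher and 1 lower, and S phase and DNA replication has none in either direction.

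Camera at its preset correlation called 9 of the 30 lists for the mean of the clones, and fry called 12. With an estimated correlation 0 were called by camera, with 5 at an unadjusted p under 0.05. Without the middle passage of every group, camera called 6 lists, of which 4 were among the 9. That fit ended the calls of the Wnt (adjusted p = 0.105), HOX (0.323), interferon (0.371), oxidative phosphorylation (0.271) and carboxypeptidase (0.0575) lists, and called the inflammatory cytokine (0.0174) and immediate early (0.0143) lists lower, with adjusted p = 0.508 and 0.757 with an estimated correlation. By clone, camera called the interferon list lower in F5 and G5 (adjusted p = 0.0331 and 0.0114) and not in H7 (0.616). With an estimated correlation the adjusted p was 0.753 in F5 and 0.597 in G5. Camera did not call the differences of F5 and G5 from H7 (adjusted p = 0.302 and 0.182). The Wnt, fibrillar collagen, chondrocyte and carboxypeptidase lists were called lower by camera in G5 (adjusted p = 0.0372 each). With an estimated correlation the adjusted p was 0.194, 0.516, 0.46 and 0.194. Camera called these lists neither in F5 (adjusted p = 0.0526, 0.229, 0.0915 and 0.0915) nor in H7 (0.344, 0.867, 0.501 and 0.0577). For none of them did it call G5 apart from F5 (adjusted p at least 0.189) or from H7 (at least 0.182).

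Each clone was then compared with the parental line, which shows how far the clones share their changes. Clone F5 had 1012 genes higher and 1084 lower. Genes called in F5 and in neither other clone included Hyi, a hydroxypyruvate isomerase, which rose from 2.55 ± 0.355 to 5.88 ± 0.607 CPM (log2 fold change 1.21, SE 0.17, adjusted p = 0.00111), and Eml2, a microtubule-binding protein, which fell from 5.03 ± 0.532 to 0.754 ± 0.411 CPM (log2 fold change −2.70, SE 0.39, adjusted p = 0.00141). Col18a1, the source of endostatin, rose by 1.21 (SE 0.28, adjusted p = 0.0166, or 0.0669 with the passage block). The calls of Dpyd, Itga7, Cemip, Pdzk1ip1 and Aldh3a1 each ended when any of at least 6 single libraries was left out, with adjusted p up to 0.122, 0.14, 0.134, 0.167 and 0.144; these highest values came without F5 passage 8, F5 passage 7, F5 passage 9, parental passage 7 and parental passage 8. The passage block also ended the calls of Dpyd (adjusted p = 0.126) and Pdzk1ip1 (0.0685). With the 6 libraries of F5 and the parental line alone, 767 genes were called in place of 2096, and the block for the order of passages gave 4226; leaving out the F5 libraries of passage 7, 8 or 9 gave 1226, 1340 and 1268.

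Clone G5 had 961 genes higher and 965 lower; limma on log2(TPM + 1) called 1130 and 526, and on log2(TPM + 0.1) 1136 and 516. Auts2, a transcriptional regulator, had 180 counts in the parental line and 0 in G5, at least 64.4-fold lower, and stood at 1.92 ± 0.899 CPM in F5. Fst, the activin antagonist follistatin, rose by 1.45 (SE 0.35, adjusted p = 0.0196), and AI662270, a non-coding RNA, rose by 2.17 (SE 0.22, adjusted p = 0.000169). The calls of Dyrk4, Cd93 and Fst ended without the G5 library of passage 8 (adjusted p = 0.0914, 0.14 and 0.0513). Those of Ccr7, Prelp and Abca1 ended without the parental library of passage 7, with log2 fold changes of −2.59, −2.26 and −2.02 in place of −4.34, −4.03 and −3.26. Counting every library, any of 9, 7 and 7 single omissions ended the calls of Ccr7, Prelp and Abca1. For Dyrk4, Cd93 and Fst the numbers were 3, 7 and 2. The passage block ended the calls of Dyrk4, Cd93, Ccr7 and Abca1 (adjusted p = 0.0628, 0.068, 0.0541 and 0.0568). With the 6 libraries of G5 and the parental line alone, 581 genes were called in place of 1926, and the block for the order of passages gave 3948; without the G5 libraries of passage 7, 8 or 9 the count was 1128, 1283 and 1214.

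Clone H7 had 1418 genes higher and 1459 lower. Ptprv, a receptor-type phosphatase and p53 target, rose there from 0.924 ± 0.325 to 8.71 ± 2.02 CPM (log2 fold change 3.22, SE 0.29, adjusted p = 4.33e-05). Cngb1, a cyclic-nucleotide-gated channel subunit, rose from 0.55 ± 0.128 to 6.56 ± 0.642 CPM, and Ceacam1, a cell adhesion molecule, and Dennd2d rose by 4.98 (SE 0.78) and 3.32 (SE 0.68), or by 6.65 without parental passage 6 and 4.36 without parental passage 7. Ralgps2, Zfp422, Dcp1b and Dchs2 had 722, 490, 271 and 183 counts in the parental line and 0 in H7, at least 266-fold, 181-fold, 97.9-fold and 63.5-fold lower; for Dchs2 the bound was 15.5-fold without the parental library of passage 7. With the 6 libraries of H7 and the parental line alone, 1561 genes were called in place of 2877, and the block for the order of passages gave 4808; without the H7 library of passage 7 the count was 1823.

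Genes of some chromosomes moved together in a clone. In H7, the median log2 fold change of the 419 expressed genes of chromosome 15 was 0.47, and 269 of them rose and 5 fell. The medians of chromosomes 18 and 16 in H7 were 0.28 and 0.24, and those of chromosomes 6 and 10 were −0.20 and −0.18. In F5, the median of the 802 genes of chromosome 7 was −0.18, and 207 of them fell and 39 rose; Eml2 and Grik5, a kainate receptor subunit, are among the genes of that chromosome that stood lower in F5 than in G5. Other shifts were shared between clones. The medians of chromosome 1 were −0.08, −0.12 and −0.11 in F5, G5 and H7. Of its genes 82, 97 and 129 fell and 35, 29 and 34 rose. Chromosome 6, lower in H7, had medians of 0.09 in F5 and 0.11 in G5. Aebp1 lies on chromosome 11, whose medians were between −0.01 and 0.06 in the 3 clones.

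**Figure D4:**
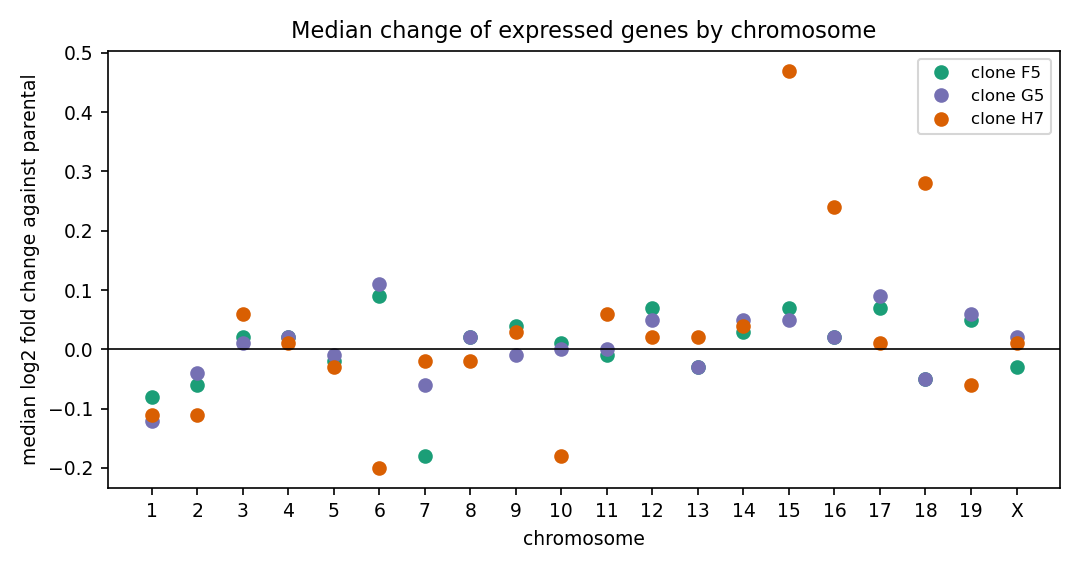
Median log2 fold change against the parental line (vertical axis) of the expressed genes of each chromosome (horizontal axis) in each clone (colour). Chromosome 15 stands at 0.47 in H7 and at 0.07 and 0.05 in F5 and G5.

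Of the genes that rose, 364 were called in F5 and G5 and not in H7, 906 in H7 alone and 374 in all 3 clones. Of those that fell, the counts were 379, 990 and 314. Opposite calls were 2 between F5 and G5, 94 between F5 and H7 and 118 between G5 and H7. Across 12923 genes, the log2 fold changes of F5 and G5 correlated with r = 0.88, those of F5 and H7 with r = 0.43 and those of G5 and H7 with r = 0.40, across genes, which are not independent replicates. In a simulation, all libraries were drawn anew at the parental means, with 1 simulated parental group shared by the clones. It gave a mean r of 0.50 for each pair. The covariances were 0.279, 0.171 and 0.178, against 0.0262, 0.0266 and 0.0267 in the simulation. F5 and G5 shared 738 higher genes where independent lists would share 66.1, F5 and H7 shared 459 against 97.6, and G5 and H7 shared 427 against 92.7. For lower genes these numbers were 693 against 71.1, 402 against 107.6 and 381 against 95.8. All 3 clones shared 374 higher and 314 lower genes where independent lists would share 6.4 and 7.1. The simulation gave 0 shared edgeR calls, which its lack of any effect all but fixes. It cannot show how much overlap shared controls give where the lines differ. The 3 parental libraries are too few to be split, so part of the excess may come from the shared controls.

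The clones were compared with each other to measure how far they differ. The edited position in each clone is not given in the sources used here, so differences between the edits may be part of what was measured. F5 and G5 differed at few genes: 28 were higher in F5 and 10 were lower, against 10 and 10 by limma on log2(TPM + 1) and 15 and 9 on log2(TPM + 0.1). Picked after their values were seen, Thbd, which encodes thrombomodulin, stood at 5.57 ± 1.95 CPM in F5 and 0.477 ± 0.177 in G5, and Sfmbt2, a polycomb-group gene, at 4.67 ± 1.57 and 0.0453 ± 0.0785. In the parental line Thbd stood at 29.5 CPM and Sfmbt2 at 13.5. DESeq2 called 102 genes between F5 and G5, the passage block called 21, the block for the order of passages 82, the 6 libraries alone 19 and the fit without the middle passages 24. Without the parental library of passage 7 the count was 57, without G5 passage 9 it was 22, without F5 passage 9 it was 25 and without G5 passage 8 it was 25.

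F5 and H7 differed at 1389 higher and 1249 lower genes, and G5 and H7 at 1305 higher and 1252 lower. For G5 and H7, limma on log2(TPM + 1) called 1417 and 736, and on log2(TPM + 0.1) 1434 and 726. Btbd11, an ankyrin-repeat protein, stood at 15.2 ± 2.08 CPM in the parental line, 20.2 ± 2.46 in F5 and 20.6 ± 0.651 in G5, and had 0 counts in H7, at least 393-fold lower than in the parental line. Mbnl3, a splicing regulator, rose from 0.616 ± 0.137 CPM to 9.64 ± 1.51 in F5 and 12.1 ± 1.16 in G5 and had 0 counts in H7. Gtpbp10, a mitochondrial GTPase, Jph1, a junctophilin, Snrpn, an imprinted splicing factor gene, and Nhs also had 0 counts in H7, at least 165-fold, 143-fold, 62.3-fold and 22.4-fold lower than in the parental line; for Nhs the bound was 14.2-fold without the parental library of passage 7. The block for the order of passages gave 4603 calls between F5 and H7 and 4356 between G5 and H7.

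Within groups, edgeR called 3 genes with a trend over the passage number: Ier2, an immediate early gene, fell by 0.32 (SE 0.03, adjusted p = 0.00845) per passage, Nr1d1, a clock repressor, fell by 0.40 (SE 0.04, adjusted p = 0.0152) and the predicted gene Gm42793 rose by 0.57 (SE 0.06, adjusted p = 0.0152). These 3 were named after their values were seen. At an unadjusted p under 0.05 there were 1042 genes, and DESeq2 called 63. Without the parental library of passage 7 the count was 21, and without any of 7 other single libraries edgeR called 0.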

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

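The tests of shared libraries and of mixing between F5 and G5, both tests on the Y-linked genes, and the count for a common origin without single libraries were chosen after the result was seen.

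The clones differed from each other. Between F5 and H7 2638 genes were called and between G5 and H7 2557, by the test of the difference itself, and 38 between F5 and G5. The fitted difference of G5 minus H7 was 12.04 on the log2 scale for Btbd11, 11.28 for Mbnl3, 10.87 for Jph1, 10.11 for Snrpn and 9.81 for Nhs, and that of F5 minus H7 was 11.06 for Gtpbp10. H7 had 0 counts of these 6 genes, so the fitted values depend on the prior count. Against 3 counts over the H7 libraries, the parental level was higher by at least 393-fold for Btbd11, 165-fold for Gtpbp10, 143-fold for Jph1, 62.3-fold for Snrpn, 22.4-fold for Nhs (14.2-fold without parental passage 7) and 15.9-fold for Mbnl3.

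The genes of chromosome 15 stood higher in H7, with a median log2 fold change of 0.47 (bootstrap SE 0.01) and 93.1% of 419 genes above 0. Library scaling and GC content or gene length are argued against: chromosome 15 lay at least 0.47 above the other autosomes in each H7 library, and after a correction for GC content and exon length the median was 0.51. A higher copy number of the whole chromosome stays open: 100% of the 7 bins of 10 Mb with at least 20 genes had a median above 0, which decides nothing where 93.1% of the genes stood above 0, and DNA was not measured. F5 and G5 stood at 0.07 and 0.05, and these values argue against an effect of the knockout of this size in every clone. A change that H7 alone acquired in cloning or in culture stays open, as does an effect of the knockout particular to H7.

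F5 and G5 differed at few genes, and one library under both names is excluded by the lowest chi-square per degree of freedom between an F5 and a G5 library, 7.99, where repeated sampling of 1 library would give about 1; the lowest value within a group was 21.1. Mixing to equal shares over the summed libraries of a clone is argued against by the upper bound of 19.8% on the share of either clone in those of the other. Smaller shares stay open, and so does equal mixing in a single library, which a bound on summed counts does not address. A common origin of F5 and G5 may account for part of the likeness: 4 genes (Lum, Prelp, Anpep and Chil1) were under 10% of the parental and the H7 level in both, where 0.01 would be found if the 6 such genes of F5 and the 22 of G5 were independent. Without parental passage 7 the number was 2, namely Chil1 and Slc14a1, so Lum, Prelp and Anpep were not among them. Without F5 passage 9 or G5 passage 7 the number was also 2. A response to the knockout that H7 lacks would give the same overlap and was not tested.

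Kdm5d, Ddx3y, Eif2s3y and Uty, on the Y chromosome, stood near 0 in all 3 clones. Sampling of few counts is excluded, since the upper 95% bound on their summed counts was 1.95% of the parental level in F5, 0.68% in G5 and 0.554% in H7. Loss of the whole Y chromosome may be the source but remains unsettled: the other tested Y-linked genes, Gm21244, Gm37158 and Gm47283, kept at least 56.2% of the parental level, and copies of them outside the chromosome were not searched. Loss in the cell that founded each clone and loss in culture were not tested.

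For the mean of the clones, 1 of 100 splits of the libraries, the real one, gave as many calls as 2800; the highest other split gave 2297 and set the H7 libraries in the parental place. For genes changed alike in all clones, 3 of 100 splits gave at least 688, the highest other gave 792, and the 2 other splits had the H7 libraries in the parental place; without these the highest was 1. Most splits mix lines and gave about 0 calls, so these splits do not exclude chance differences between the 4 lines. Apart from the real one, the splits with H7 were the only ones drawn that kept a whole line in the parental place. They therefore cannot show whether H7 stands apart more than F5 or G5 would. For the lists called by camera, 18 of 100 splits gave at least 9, so chance is not excluded. The highest other gave 12, and the median of the other splits was 6. The comparisons of 3 libraries with 3 have 10 splits each, too few for a share under 0.05. The real split, 1 of 10, gave 2096 calls for F5 against the parental line (highest other 2), 1926 for G5 (0), 2877 for H7 (0), 38 for F5 against G5 (0), 2638 for F5 against H7 (0) and 2557 for G5 against H7 (0).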

How the results depend on the processing

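The block by place in the order of passages, its use with an estimated correlation, the removal of chromosome medians, the fit without the middle passages, the lists between clones or with an estimated correlation without single libraries, and the carboxypeptidases without Aebp1 were chosen after the result was seen. Of 4798 values of 162 named results under 31 alternatives, 4261 kept their side of the threshold, 505 lost the call and 30 gained it. The other 2 changed direction with a call in the main fit. Both were Hoxc8 in the mean of the clones, at 0.36 with the knockout libraries as 1 group and 0.37 with counts summed per line. Changes of direction without a call in either fit were counted among the 4261. Mcm2, for instance, went from 0.18 to −0.01 without parental passage 7. At an adjusted p under 0.01 the counts were 1259 for the mean of the clones, 834 for F5, 782 for G5, 1461 for H7, 20 for F5 against G5, 1330 for F5 against H7, 1339 for G5 against H7, 256 for all 3 clones and 1 for the passage trend. With an absolute log2 fold change of at least 1 they were 664, 575, 611, 803, 35, 710, 729, 196 and 0 (edgeR; without the fold threshold 3 genes, DESeq2 63, 1042 at an unadjusted p under 0.05). Both thresholds are stricter by construction. On 6 libraries, F5, G5 and H7 gave 767, 581 and 1561, F5 against G5 19 and all 3 clones 219. With 1 knockout group the mean of the clones gave 1356; summed per line, edgeR called 0 (DESeq2 650; 1735 at an unadjusted p under 0.05) and Aebp1 stood at −1.81 without a call, with 3 clones against 1 line. The order block gave 4908, 4226, 3948, 4808, 82, 4603, 4356 and 1546 for the comparisons above without the passage trend, which could not be fitted under it. F5 against G5 gave 102 by DESeq2, 20 and 24 by limma on log2(TPM + 1) and log2(TPM + 0.1), 24 without the middle passages and 21 with the passage as a replicate block. That block ended the calls of 17 named results, among them Nes, Twist2, Sqle, Pdgfrb, Lss and Egr3 in the mean of the clones, and began that of Nfe2l2 (adjusted p = 0.0287). It began the call of the list of inflammatory fibroblast cytokines (0.0382), changed no other call of a named result or list and moved no other count of calls by over 1.5 times. Libraries of the parental line and a clone with the same passage number correlated between −0.53 and −0.19 over 6 pairs, so the number does not pair them. Libraries with the same place in the order correlated between 0.04 and 0.50 over 9 pairs. The order block kept 155 of the 162 named results on their side of the threshold and began the calls of 7. Camera with an estimated correlation called 0 lists (5 at an unadjusted p under 0.05), and 0 with the order block; fry called 12, the passage block and the order block 10 each, library sizes in place of TMM factors 6 and a prior count of 0.5 gave 8, against 9. With each clone's chromosome medians removed, 151 of the 162 named results kept their side of the threshold and 11 lost the call. The cause was not tested for results that moved otherwise. Leaving out each library in turn gave 2099 to 2756 for the mean of the clones, 1226 to 2142 for F5, 1128 to 2044 for G5, 1823 to 2822 for H7, 22 to 57 for F5 against G5, 1767 to 3635 for F5 against H7, 1754 to 3458 for G5 against H7, 456 to 759 for all 3 clones, 0 to 21 for the passage trend and 8 to 12 lists. Without parental passage 7, 11 lists were called, of which 5 were among the 9. That fit removes the middle passage from the parental line and keeps it in the clones. The lowest counts for F5, G5, H7 and all 3 clones came without F5, G5, H7 and H7 passage 7, and that for F5 against G5 without G5 passage 9; the highest for the last and for the passage trend came without parental passage 7. The Aebp1 log2 fold change lay between −1.95 and −1.76 for the mean, −1.63 and −1.44 in F5, −2.21 and −2.03 in G5 and −2.02 and −1.83 in H7. Depth limits genes near the floor of 3 counts over a group.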

Other observations

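The comparison of middle passages, the imprinted genes and the mitochondrial genes were chosen after the result was seen.

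In a fit with terms for the passage order shared by the 4 groups, the middle passages differed from the mean of the first and the third. EdgeR called 2432 genes higher and 2290 lower in this pooled test, and no group was tested alone. Hlf, a circadian transcription factor, rose by 3.07 (SE 0.19, adjusted p = 3.56e-05) on the log2 scale, Cemip, a hyaluronan-degrading protein, by 1.98 (SE 0.11), Igf2 by 2.20 (SE 0.25) and H19 by 2.21 (SE 0.27). Prl2c2, a proliferin, fell by 2.37 (SE 0.15, adjusted p = 3.56e-05), Mt2, a metallothionein, by 1.53 (SE 0.18) and the growth factor Fgf2 by 1.40 (SE 0.24). Of 32 genes of S phase 30 fell, and of 32 genes of G2 and mitosis 31 fell (31 and 31 adjusted over the list alone; adjusted p = 0.473 with an estimated correlation for both). Of the other extracellular matrix proteins, 20 of 36 rose and 2 fell, and of the interferon-stimulated genes 12 of 21 rose and 1 fell (21 and 2, and 13 and 1, adjusted over the list alone; adjusted p = 0.473 with an estimated correlation for both). The third against the first passage gave 164 calls. The labels do not say what the middle passages share.

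Of 16 imprinted genes, 9 were called lower in the mean of the clones, Igf2 and H19 among them, or 7 without parental passage 7. The other 7, Meg3, Rian, Usp29, Ndn, Grb10, Igf2r and Impact, were not called for the mean, with adjusted p between 0.06 and 0.609. No test of the group was made. By clone, edgeR called 2 of the 16 higher and 7 lower in F5, 2 and 5 in G5, and 0 and 10 in H7. Snrpn, 1 of the 9, rose by 0.79 in F5 and 1.16 in G5 (adjusted p = 0.0115 and 0.00193) and had 0 counts in H7. Mest had 128 counts in the parental line and 0 in each clone, at least 49.8-fold lower in F5, 44.8-fold in G5 and 46.1-fold in H7. Rtl1 fell by 2.11 (adjusted p = 0.00161) and Peg3 by 0.97 (adjusted p = 0.00407) in the mean of the clones. In G5 Peg3 stood at −0.07 (adjusted p = 0.894). Without parental passage 7 Rtl1 stood at −1.52 and Peg3 at −0.62 in the mean. Usp29 fell in H7 by 3.22, from 1.12 ± 0.364 to 0.117 ± 0.0694 CPM. Of 15 mitochondrially encoded genes, 9 were lower in F5 than in H7 and 7 lower in G5 than in H7. The H7 library of passage 9 had 4.00% of its counts in these genes, against 2.68% and 2.95% in the other H7 libraries, and without it the numbers were 5 and 3. Without F5 passage 7, 8 or 9 the first number was 3, 5 and 4, and without G5 passage 7 or 8 the second was 3.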
